A study of Mus musculus with 4 samples.

How the data were processed

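RNA of fetal forebrain and hippocampus at embryonic day 18 was measured on 4 Affymetrix mouse gene arrays, 1 for each tissue after maternal PBS or ethanol. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made from 6 ug of it. The submitters' processing notes name MAS5, and its version, the background correction, the summarization and the normalization are not given in the sources used here. The expression values are the authors' deposited log2 values: the labels do not state the scale, and it was read from the values, which run from 1.58 to 13.96. On a natural-log scale the highest would exceed 1.07e+06, above the 65535 that a 16-bit scanner can record. Array medians and quantiles lie close together without being equal, and genes are not centred. The analysis had allowed for linear MAS5 signals with a pseudocount, and none was needed. Samples were grouped by tissue and treatment from their titles.

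Probe sets were named through the platform's annotation table, with symbols checked against a RefSeq table of assembly GRCm38.p6. Of 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none, and only those with 1 symbol were named. For 21698 of them the gene identifier was in the RefSeq table, and 0 symbols changed. No genome was used, so positions are not reported. For each of 19938 genes the probe set with the highest mean was taken, and 11013 genes whose mean reached the median of all probe set means (7.11) were kept. Of these, 822 had more than 1 probe set. The authors' scaling was kept.

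Within a tissue, ethanol and PBS were compared by the difference of log2 values of 2 arrays, counted at 2-fold, with 1.5-fold and 3-fold as alternatives, and without a test. Over both tissues, limma 3.58.1 in R 4.3.3 was fitted with treatment and tissue as additive terms, eBayes with a trend and Benjamini-Hochberg adjustment at 0.05. The fit leaves 1 residual degree of freedom, so the treatment-by-tissue difference serves as error, and its p-values measure the spread between these arrays. A count of genes shared by the tissues stands beside the number that independent lists would share. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

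The gene groups were fixed before the data were examined. They are excitatory neuron transcription factors, GABAergic interneuron lineage, axon guidance and cell adhesion, synapse and neurotransmission, radial glia and neural progenitors, cell cycle, apoptosis and p53 targets, alcohol, aldehyde and retinoid metabolism, oxidative stress, unfolded protein and heat shock response, glycolysis and hypoxia, neuropeptides, immediate early genes, Wnt signalling, imprinted growth genes, DNA methylation and chromatin, neuronal RNA-binding proteins, and cholesterol and fatty acid synthesis. Markers were also listed for hippocampal fields, striatal projection neurons, thalamus and hypothalamus, Cajal-Retzius cells, choroid plexus, erythroid cells, meningeal fibroblasts, endothelial cells, pericytes and smooth muscle, microglia and macrophages, astrocytes, the oligodendrocyte lineage and the sexes. Neurog2, Fezf2, Ntng1, Gal and Nova1 were placed in these groups partly because the study is remembered to have named them, and Gal fell below the expression filter. Some genes stand in several groups, such as Calb2 in 3. A list with at least 5 kept genes was described by its median difference and the percentile of that median among 10000 random lists of the same size matched on mean expression in 10 bins. A percentile under 2.5 or over 97.5 was called apart, which chance gives for 5% of lists. Random lists do not carry the correlation of related genes, so this share is a lower limit for real groups. A second striatal and a second cortical projection neuron list, a histone list, a small nucleolar RNA list and a group of all kept microRNA genes, by symbol, were added after the main results had been seen.

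The genes named were chosen by a rule fixed before the data were examined, among kept genes other than those with predicted or clone names. It takes the 8 highest and 8 lowest ethanol differences in each tissue, up to 8 per direction among genes 2-fold apart in the same direction in both tissues, up to 10 per direction among genes 2-fold apart between tissues in both treatments, the 5 highest and 5 lowest differences between the tissues' ethanol effects, and up to 6 members per list with the largest absolute difference. The part on both tissues gave no gene and the part on tissues gave Gjb2. Genes called by limma and others outside the rule are said to have been chosen after their values were seen, and this includes those called over a list alone.

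The scripts were tested on simulated values for 11013 genes, 200 of them changed. The limma fit over both tissues recovered 100% of 2-fold and 100% of 1.5-fold genes and called 14 unchanged genes. In the simulated comparison of 2 hippocampus arrays 0 unchanged genes were 2-fold apart and 20 were 1.5-fold apart. Of unshifted lists 4.5% were called apart, and of lists shifted by 0.2 log2 units 100%. The simulated noise was independent between genes and held no tissue-specific response, so recovery in the real arrays can be lower.

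Alternatives chosen before the data were examined were no expression filter, a filter at the 75th percentile, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, the other fold thresholds, eBayes without a trend and an adjusted p of 0.1. Pseudocount settings did not apply to log2 values, and leaving out an array was not possible with 1 array per group.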

Results

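Gene expression was measured in fetal brain tissue of C57BL/6J mice whose dams had received ethanol or phosphate-buffered saline (PBS). Ethanol was given at 2.9 g per kg per day as a 15% solution into the stomach, on 5 days from embryonic day 8 to day 12, and tissue was collected on embryonic day 18. The 4 groups were forebrain after PBS, forebrain after ethanol, hippocampus after PBS and hippocampus after ethanol, with 1 array each, so that no difference within a tissue has a replicate check or a p-value. Whether the RNA of several embryos was pooled, and whether both tissues came from the same embryos, is not in the labels. Litters are not given either. A difference between litters or processing runs that goes with treatment therefore cannot be told apart from ethanol. Over all 35557 probe sets the array medians lay between 7.11 and 7.13 on the log2 scale. Among the 11013 genes kept, the hippocampus array after ethanol had a median of 8.57 and the other arrays had medians of 8.66 to 8.68, and the number of arrays limits the precision of every value.

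The first comparison asked which genes differ after maternal ethanol in the fetal tissue labelled hippocampus, in particular those of nervous system development. Markers of hippocampal fields did not set this tissue apart from forebrain, as given below, so expression does not bear out its label. In the ethanol array Cdhr1, a cadherin-related protein best known from photoreceptors, read 7.99 against 6.13 in the PBS array, a difference of 1.86 on the log2 scale. The growth factor gene Igf1 was higher by 1.08, Cpne6, a calcium-dependent phospholipid-binding protein of neurons, by 1.07, the protocadherin gene Pcdh11x by 1.06 and Cbln2, a secreted organizer of synapses, by 1.03. Next came the eye and body-wall development gene Mab21l2 at 0.98, the secretogranin gene Scg2 at 0.95 and the long non-coding RNA host gene Snhg11 at 0.95. For all of these but Mab21l2 the hippocampus PBS array stood apart, and the hippocampus ethanol array read near both forebrain arrays. Scg2, for example, read 8.70 and 8.77 in forebrain, and 7.64 after PBS and 8.59 after ethanol in hippocampus. A deviation of that single PBS array cannot be told apart from a rise with ethanol. On the lower side, Met, the hepatocyte growth factor receptor, differed by -0.92, the glypican gene Gpc4 by -0.91, the neurotensin receptor gene Ntsr1 by -0.91, the Wnt ligand gene Wnt7b by -0.88 and Sox5, a transcription factor of deep-layer cortical neurons, by -0.85. Adamts3, a secreted metalloprotease gene, differed by -0.84, with all 16 of its probe sets lower in the ethanol array, and the histone H4 gene H4c6 differed by -0.83. A probe set assigned to the microRNA gene Mir19b-1 differed by -1.09, which is not a measure of the mature microRNA. Some of these differences involve a reading below the filter value of 7.11, which was applied to the mean over arrays. Such readings were Cdhr1 (6.13), Igf1 (6.65), Cpne6 (7.09) and Mab21l2 (6.49) in the PBS array and Mir19b-1 (6.70) in the ethanol array.

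In hippocampus 6 genes were at least 2-fold higher and 1 was at least 2-fold lower after ethanol, which became 10 and 0 with each array centred on its median, 3 and 0 with the 75th percentile filter and 10 and 1 without a filter. At 1.5-fold these counts were 54 and 47. The split of the 1.5-fold genes depended on the setting: 116 higher and 19 lower with each array centred on its median, and 88 higher and 31 lower after quantile normalization. They were 23 and 30 with the 75th percentile filter and 131 and 77 without a filter. The median difference over all kept genes was -0.08 and the standard deviation of the differences 0.187, against 0.0941 in forebrain. Across kept genes the hippocampus ethanol array had a Pearson r of 0.985 with the hippocampus PBS array, 0.988 with the forebrain PBS array and 0.989 with the forebrain ethanol array, and the hippocampus PBS array had 0.987 and 0.983 with the same forebrain arrays, where genes are not independent replicates.

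**Figure D1:**
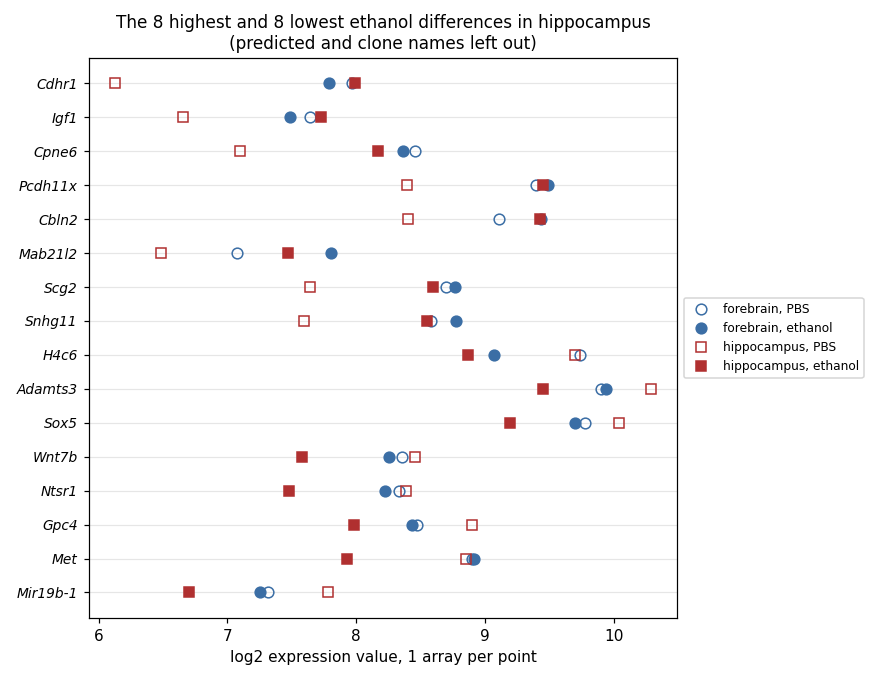
Log2 expression values (horizontal axis) of the 8 genes with the highest and the 8 with the lowest ethanol differences in hippocampus, predicted and clone names left out, 1 point per array: circles forebrain, squares hippocampus, open PBS, filled ethanol. Cdhr1 moves from 6.13 to 7.99 between the hippocampus arrays and reads 7.96 and 7.79 in forebrain, while Mab21l2 is higher after ethanol in both tissues. Cdhr1, Igf1, Cpne6, Pcdh11x, Cbln2, Scg2 and Snhg11 read low in the hippocampus PBS array alone.

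Neuronal gene groups of the hippocampus array moved in different directions after ethanol. All 14 measured markers of striatal projection neurons were higher, with a median of 0.37 (percentile 100 among 10000 random lists matched on expression), led by the retinoic acid receptor gene Rarb at 0.72, the neuropeptide precursor genes Tac1 at 0.66 and Penk at 0.63 and the transcription factor gene Ebf1 at 0.54. Of 17 genes of the GABAergic interneuron lineage, 13 were higher and 4 lower, with a median of 0.19 (percentile 100). Among them the calcium-binding protein gene Calb2 differed by 0.87, somatostatin (Sst) by 0.63 and the GABA-synthesizing enzyme gene Gad1 by 0.51, whereas the chemokine receptor gene Cxcr4 differed by -0.44. Thalamic and hypothalamic markers were higher for 8 of 9 genes (median 0.30, percentile 100), led by Calb2, which 3 of the lists share, and Tcf7l2, a thalamic transcription factor gene, at 0.84. In contrast, 22 of 26 transcription factor genes of excitatory neurons were lower (median -0.35, percentile 0), 7 of them by 1.5-fold or more, including Sox5, Nfia at -0.70, Lhx2 at -0.67 and Fezf2 at -0.65. Wnt signalling genes were lower for 14 of 16 (median -0.21, percentile 0.14), with the ligand gene Wnt7b at -0.88, the agonist gene Rspo3 at -0.54 and the inhibitor gene Sfrp2 at -0.39. The Wnt median stood apart from random lists under 4 of 5 alternatives, among them array centring, which cannot change the call.

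Genes of dividing and non-neuronal cells also differed between these arrays. Cell cycle genes were lower for 24 of 25 members (median -0.20, percentile 0.16), such as the mitotic kinase genes Bub1 at -0.47 and Plk1 at -0.37, and radial glia and progenitor genes for 12 of 18 (median -0.16, percentile 0.92), such as the transcription factor gene Gli3 at -0.54 and the intermediate filament gene Nes at -0.48. The call for progenitor genes was lost under 1 alternative. Choroid plexus markers were lower for 8 of 9 genes (median -0.26, percentile 0.17), including Clic6 at -0.48 and the water channel gene Aqp1 at -0.42. Meningeal fibroblast markers were higher for 12 of 14 (median 0.29, percentile 100), with the proteoglycan gene Dcn at 0.73, the transporter gene Slc6a13 at 0.59 and the collagen gene Col3a1 at 0.50. Astrocyte markers were higher for 8 of 9 (median 0.20, percentile 100), led by the lipoprotein gene Apoe at 0.55 and the water channel gene Aqp4 at 0.50, and imprinted growth genes for 10 of 14 (median 0.23, percentile 100), led by Peg10 at 0.57 and Zim1 at 0.47. Neuropeptide genes had 6 of 11 members higher (median 0.09, percentile 99.5), among them Tac1, Sst and Penk, which other lists hold too, and this median was -0.01 under the stricter expression filter. Synaptic genes stood at a median of 0.02, with 12 higher and 11 lower, above most random lists (percentile 99.5), while the median over all kept genes was -0.08. The same ethanol array read lower for Y-linked genes, with Uty at -0.35, Eif2s3y at -0.33 and Kdm5d at -0.26, and for 36 of 38 small nucleolar RNA genes, a group assembled after values were seen (median -0.32).

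Because the ethanol array had a lower median over kept genes, centring each array brought several of these medians nearer to 0 or raised them. Which lists stand apart from random lists cannot change with centring, since it shifts all genes of an array alike. The cell cycle median was then -0.10 (-0.12 after quantile normalization), that of choroid plexus markers -0.16, Wnt genes -0.12, progenitor genes -0.06, GABAergic genes 0.29, neuropeptides 0.19 and synaptic genes 0.12.

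No displacement from random lists was seen in hippocampus for the other groups with enough members. Hippocampal field genes had a median of -0.03 (4 higher, 5 lower), axon guidance genes -0.09, Cajal-Retzius markers -0.08, endothelial markers -0.09, pericyte markers 0.05, microglial markers 0.01 and oligodendrocyte lineage markers 0.09. The median was -0.14 for apoptosis and p53 targets, -0.05 for alcohol, aldehyde and retinoid metabolism, -0.02 for the oxidative stress response, -0.03 for the unfolded protein response, -0.08 for glycolysis and hypoxia, -0.06 for immediate early genes, -0.14 for DNA methylation and chromatin, -0.06 for neuronal RNA-binding proteins and -0.06 for cholesterol and fatty acid synthesis. Single members of these groups still stood out, such as the netrin-related gene Ntng1 at 0.84, the ephrin receptor gene Epha3 at -0.65, the retinoid X receptor gene Rxrg at 0.67, the splicing regulator gene Nova1 at 0.86 and the maintenance methylation factor gene Uhrf1 at -0.54. Erythroid markers kept only 3 genes (median -0.15) and sex-linked genes 4, too few to be set against random lists. In all, 13 of 29 lists stood apart in hippocampus, 8 higher and 5 lower, where chance alone would give 1.45. The random lists ignore that genes of a group vary together, and the members Neurog2, Fezf2, Ntng1, Nova1 and Gal were listed partly from recollection of the study itself, so these members are not independent evidence of a direction.

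In forebrain the differences after ethanol were smaller. The Y-linked genes Eif2s3y, a translation factor subunit, and Uty, a histone demethylase relative, were higher by 0.89 and 0.79, and the Y-linked demethylase gene Kdm5d by 0.57, while the X-inactivation RNA Xist differed by -0.38. Mab21l2 was higher by 0.73, Ebf3, a transcription factor gene of Cajal-Retzius cells, by 0.68, the cerebellin gene Cbln4 by 0.52 and Tcf7l2 by 0.47. A probe set assigned to the microRNA gene Mir692-1 read 0.58 higher, again not a measure of the mature RNA. On the lower side 5 of the 8 genes encode histones: H4c6 at -0.66, H2bc3 at -0.60, H4c4 at -0.51, H2bc18 at -0.45 and H1f1 at -0.39. The others were the RNA-binding protein gene Igf2bp1 at -0.59, the chaperone gene Dnajb6 at -0.50 and the centrosomal gene Cep76 at -0.40. Histone genes are near-identical copies, so their probe sets may not be told apart from each other. No gene was 2-fold apart in either direction, while 5 were at least 1.5-fold higher and 3 lower. With arrays centred on their medians the 1.5-fold genes numbered 6 higher and 1 lower, and after quantile normalization 5 and 2, against 1 and 1 with the 75th percentile filter and 24 and 22 without a filter.

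Glial and several other groups stood apart in forebrain by small amounts. Oligodendrocyte lineage markers were higher for 8 of 9 genes (median 0.14, percentile 100), with the transcription factor gene Olig1 at 0.30 and Gpr17 at 0.23, and astrocyte markers for 7 of 9 (median 0.11, percentile 100), with Aldh1l1 at 0.18 and Aqp4 at 0.16 (median 0.07 after quantile normalization). Imprinted growth genes (median 0.08, 10 of 14 higher), thalamic and hypothalamic markers (0.08, 7 of 9), choroid plexus markers (0.08, 7 of 9, with Otx2 at 0.33) and oxidative stress genes (0.05, 11 of 16) were also higher than random lists. Lower were meningeal markers (-0.11, 13 of 14 lower, with Foxd1 at -0.29), GABAergic genes (-0.09, 12 of 17, with Lhx6 at -0.25), cell cycle genes (-0.07, 23 of 25, with Ccnb2 at -0.24), alcohol, aldehyde and retinoid genes (-0.07, 11 of 14, with Rxrg at -0.39; -0.18 with the 75th percentile filter) and excitatory neuron factors (-0.05, 20 of 26, with Fezf2 at -0.22; -0.03 with centred arrays). Striatal markers had a forebrain median of -0.03, with 5 higher and 9 lower. These 11 of 29 lists compare with 1.45 by chance, and the calls for choroid plexus, cell cycle and retinoid genes were lost under 1 alternative each.

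**Figure D2:**
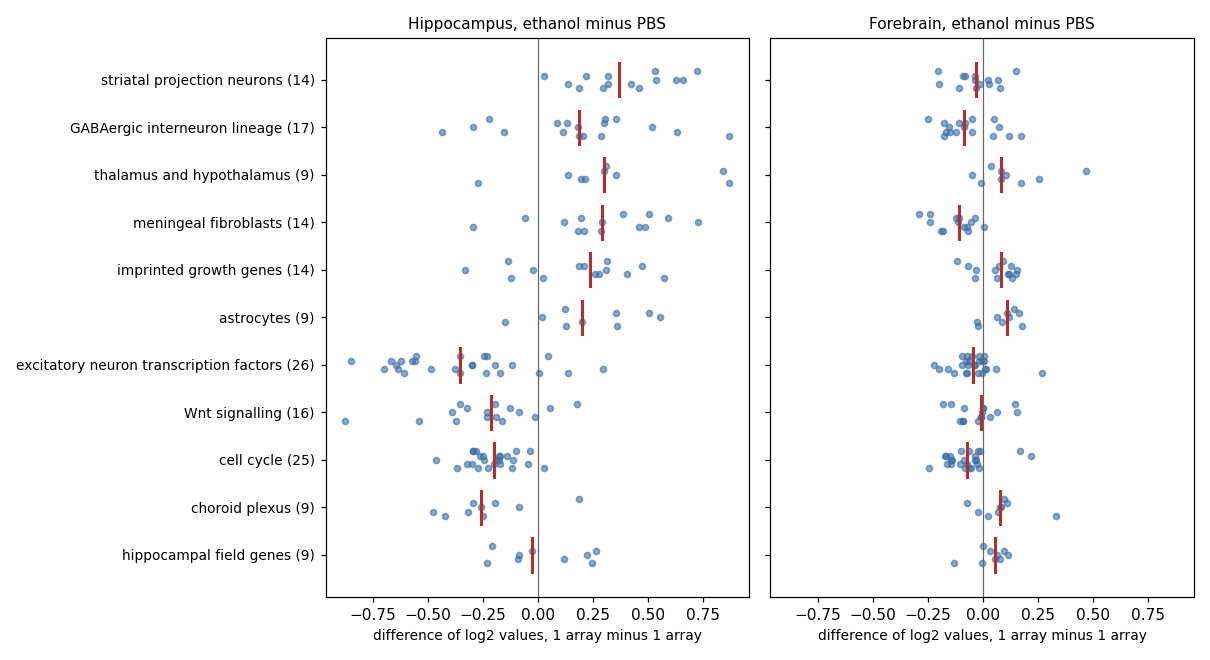
Differences of log2 values, ethanol minus PBS (horizontal axes), for the members of 11 gene lists in hippocampus (left) and forebrain (right): each point is a gene, the vertical bar is the median of its list, and the number of genes kept stands in parentheses. Striatal markers lie at a median of 0.37 in hippocampus and -0.03 in forebrain, and excitatory neuron factors at -0.35 and -0.05.

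Set side by side, the responses of the tissues shared few large differences. At 1.5-fold, Ebf3 and Mab21l2 were higher and H4c6 lower in both, named here after their values were seen, where independent lists would share 0.0245 and 0.0128 genes. At 2-fold no gene was shared, and no gene was 1.5-fold apart in opposite directions. Differences of the same sign that fell short of 1.5-fold in at least 1 tissue were seen for Tcf7l2 (0.84 in hippocampus), Cbln4, Igf2bp1 (-0.55 in hippocampus, both probe sets lower) and H4c4 (-0.51 in each). Over all kept genes the ethanol differences of the tissues had the same sign in 61.4% and correlated across genes at r = 0.321. These comparisons share no array, but both tissues of a treatment may come from the same litters. Agreement between the tissues is therefore not an independent repeat of the ethanol treatment.

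When ethanol was tested over both tissues with limma, with tissue as a block and Benjamini-Hochberg adjustment, 0 genes rose and 0 fell at an adjusted p of 0.05, and the lowest adjusted p was 0.104. At an unadjusted p of 0.05, limma gave 375 higher and 700 lower genes where chance gives 551 in all. The mean ethanol difference had a median of -0.04 over all kept genes. The lean toward lower genes therefore cannot be told apart from an offset between arrays. Adjusted over the list alone, Aqp4, Aldh1l1, Sparcl1 and Apoe rose among 9 astrocyte markers, Tcf7l2 and Calb2 among 9 thalamic and hypothalamic markers, Ntng1 and the growth cone gene Gap43 among 30 axon guidance genes and Nova1 among 20 RNA-binding protein genes. Ebf3 and Calb2 rose and Cxcr4 fell among 6 Cajal-Retzius markers, and Calb2 rose while Npy and Cxcr4 fell among 17 GABAergic genes. Ntng1 and Nova1 are among the recalled genes, so their calls over the list alone are not independent evidence, and no correction was made across the lists. None passed in the striatal or excitatory neuron lists. Other settings gave calls over all genes: quantile normalization 12 rose and 2 fell, the 75th percentile filter 5 and 2, and median centring 1 and 1. H4c6 and Mir692-1 were called in each of these settings, and H4c4, Nova1, Tcf7l2, Rit2 and Rab2a in the first pair of them. The fit has 1 residual degree of freedom, and a response that differs between tissues counts as error in it. Its arrays per treatment are different tissues that may share litters, not repeats of the treatment.

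The comparison of tissues, over both treatments, describes how the dissected regions differ. Lower in hippocampus were the cystine transporter gene Slc7a11 by limma's -1.16 (SE 0.135, Benjamini-Hochberg adjusted p = 0.0203), the huntingtin-associated protein gene Hap1 by -1.11 (adjusted p = 0.0175), the connexin gene Gjb2 by -1.10 (adjusted p = 0.0175), the meningeal transporter gene Slc6a13 by -1.08 (adjusted p = 0.0348) and the retinoic acid synthesis gene Aldh1a2 by -0.99 (adjusted p = 0.0175). The transcription factor genes Zic1, Zic2, Zic4 and Zic5 were lower too, at -0.80, -0.81, -0.69 and -0.63. Higher in hippocampus were Nexn, an actin-binding protein gene, by 0.89 (SE 0.101, adjusted p = 0.0190), Ebf1 by 0.85 (adjusted p = 0.0384), Strip2 by 0.78 (adjusted p = 0.0179), the ephrin receptor gene Epha4 by 0.57 (adjusted p = 0.0175) and Foxp1 by 0.55 (adjusted p = 0.0383), and among smaller differences the proliferation marker Mki67 by 0.45 (adjusted p = 0.0472). Ebf1 and Foxp1 are also members of the striatal marker list. In total 12 genes were higher and 112 lower in hippocampus by limma, 2 arrays against 2. With median centring the split was 21 and 45, after quantile normalization 70 and 346, without a trend in the variance 2 and 25, and without a filter 4 and 33, so that most calls end in the last pair of settings. Gjb2 alone was 2-fold apart in both treatments, at -1.01 and -1.18. The other genes of this paragraph were chosen from the limma calls after their values were seen. Every one had the same sign in both treatments, but this is no separate check. The fit counts a difference between treatments as error, so a call nearly requires the same sign.

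Region and cell type lists differed between the tissues as follows. Meningeal fibroblast markers were lower in hippocampus for 14 of 14 genes in each treatment (medians -0.99 after PBS and -0.53 after ethanol, percentile 0), with 8 passing limma over all genes and 14 adjusted over the list alone. Imprinted growth genes were lower for 13 of 14 and 14 of 14 (medians -0.38 and -0.31), with Igf2, which the meningeal list holds too, at -0.91 and -0.64, and 12 passed adjusted over the list alone. Endothelial markers (-0.20 and -0.26), synaptic genes (-0.14 and -0.17, with Slc17a7 at -0.64 and -0.61), Cajal-Retzius markers (-0.14 and -0.18) and cholesterol genes (-0.09 and -0.13) were lower in both treatments. Cell cycle genes were higher in hippocampus for 24 of 25 and 21 of 25 (medians 0.27 and 0.15), with 10 passing adjusted over the list alone, 9 of these higher, and progenitor genes also (0.13 and 0.03). After ethanol the calls for progenitor and cholesterol genes were each lost under 1 alternative. The markers of the hippocampus itself did not stand apart in either treatment (-0.05 and -0.13, percentiles 17.1 and 11.2): the zinc finger gene Zbtb20 was higher at 0.35 and 0.23, whereas Nrp2 was lower at -0.85 and -0.48 and the dentate gene Prox1 at -0.16 and -0.33. The tissue comparison was also planned as a check of the tissue labels, and these markers do not bear out the hippocampus label.

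For other groups the difference between tissues was not alike in the treatments. Striatal markers were at a hippocampus-minus-forebrain median of 0.07 after PBS (percentile 95.9) and 0.47 after ethanol (percentile 100), with Rarb at 0.25 and 1.18 and Ebf1 at 0.57 and 1.14. Excitatory neuron factors were at 0.25 (percentile 100) and -0.05 (percentile 56.9), GABAergic genes at -0.14 (percentile 0) and 0.07 (percentile 100) and choroid plexus markers at 0.37 (percentile 100) and 0.03 (percentile 92.7). After PBS only, lower than random lists were astrocyte markers (-0.25), thalamic and hypothalamic markers (-0.21), microglial markers (-0.22, and -0.10 without the expression filter) and unfolded protein genes (-0.07). After ethanol only, immediate early genes (0.04) and DNA methylation and chromatin genes (0.01) were higher, the latter at -0.03 under the stricter expression filter. The call for unfolded protein genes was lost under 1 alternative and that for immediate early genes under 2. Whether the treatments differ in these groups was not tested, since each treatment has 1 array per tissue, and the hippocampus PBS array also enters the ethanol comparison in hippocampus. With centred arrays the medians after ethanol moved by over 1.5 times for endothelial markers (-0.17), synaptic genes (-0.08), Cajal-Retzius markers (-0.09), cholesterol genes (-0.04), cell cycle genes (0.24), progenitor genes (0.12), GABAergic genes (0.16), immediate early genes (0.13) and chromatin genes (0.10). In all, 15 of 29 lists stood apart after PBS and 12 after ethanol.

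**Figure D3:**
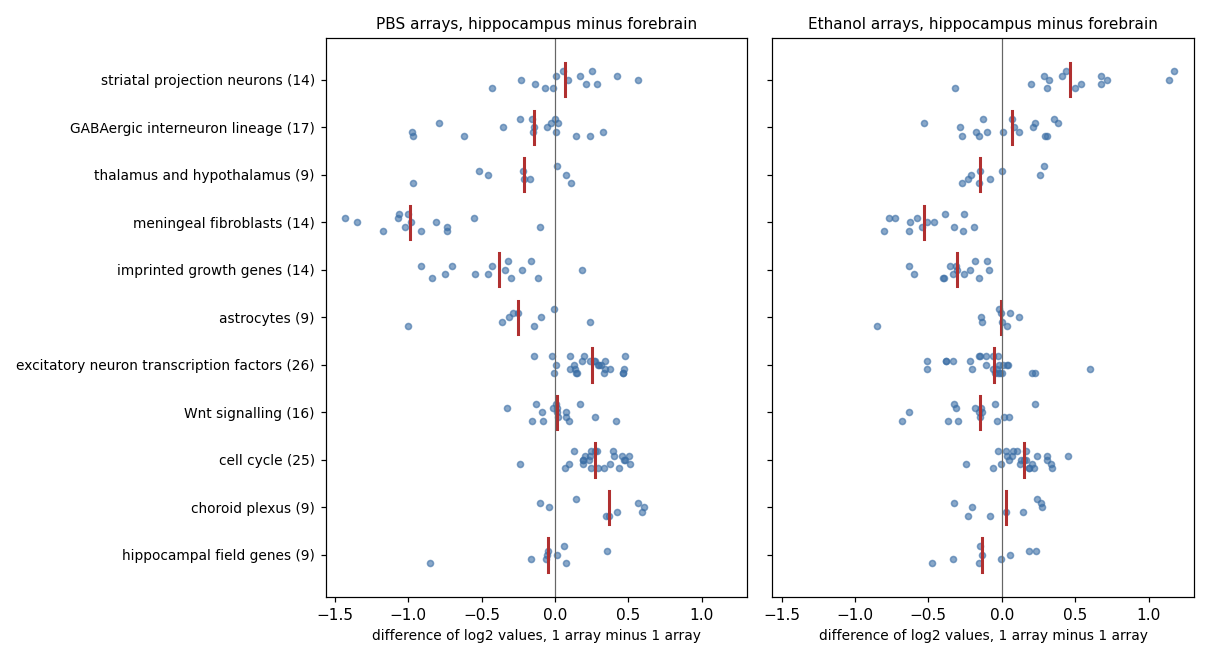
Differences of log2 values, hippocampus minus forebrain (horizontal axes), for the same 11 gene lists in the PBS arrays (left) and the ethanol arrays (right): each point is a gene and the vertical bar is the median of its list. Meningeal markers lie below 0 in both panels, with medians of -0.99 and -0.53, and striatal markers lie at 0.07 and 0.47.

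As a yardstick, the 4 arrays were split in each of the 3 ways into 2 and 2. By treatment 0 genes had a mean difference of 1 log2 unit or more, by tissue 6, and by the remaining split, which pairs each tissue of a treatment with the other tissue of the other treatment, 1. At 1.5-fold these numbers were 10, 79 and 3.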

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

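The tests on the second striatal and second cortical lists were set out after the main results but before the medians of these lists were seen. Some values of the second cortical list were in those main results. Slc17a7 is also in the synapse list, and Nrgn is among the limma calls between tissues. Every other test in this part was chosen only after the result was seen. The short RNA test first joined both tissues under a bound of -0.05 in either and argued against that explanation throughout; its bounds were then set again for each tissue, with all values known, which opened it for hippocampus. The differences between tissues given here were not tested, since each tissue and treatment has 1 array.

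Several genes stood out because their ethanol differences lay far apart in the 2 tissues. The ethanol difference in hippocampus minus that in forebrain was 2.03 log2 units for Cdhr1, 1.22 for Igf1, 1.17 for Cpne6, 1.05 for Rxrg and 1.04 for Rasgrp1. It was -1.22 for Eif2s3y, -1.14 for Uty, -1.02 for the probe set of Mir19b-1, -0.94 for Met and -0.87 for Adamts3, which were near 0 in forebrain (0.02 and 0.04, the latter with 1 of 16 probe sets higher). Among gene lists that stood apart in both tissues with opposite signs, the same quantity was -0.34 for choroid plexus markers, 0.40 for meningeal fibroblast markers and 0.27 for the GABAergic interneuron lineage. Outside the named genes, 9 of 4746 probe sets without a gene symbol were at least 2-fold higher after ethanol in hippocampus and 8 at least 2-fold lower.

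In the hippocampus arrays striatal markers were higher and excitatory neuron factors lower after ethanol, and in the same arrays thalamic and hypothalamic markers (median 0.30, 8 of 9 higher), meningeal markers (0.29, 12 of 14 higher) and choroid plexus markers (-0.26, 8 of 9 lower) differed while hippocampal field genes were at -0.03. Array scaling as the whole cause of the higher striatal markers is argued against by a striatal median of 0.44 after quantile normalization. The hippocampus ethanol array had a lower median over kept genes, so rescaling could hardly lower that value. Excitatory neuron factors, which were not part of this test, had medians from -0.35 to -0.26 over the settings run. An ethanol response common to both tissues is argued against for the striatal markers by a forebrain median of -0.0334. The excitatory neuron factors meet the same bound, which asks for a far smaller forebrain median and quartiles that do not overlap. Their quartiles were -0.078 and -0.006 in forebrain and -0.60 and -0.20 in hippocampus. A smaller response common to both tissues stays open for them, since 20 of 26 were lower in forebrain too (median -0.05, percentile 0.48). A loss of excitatory neurons alone could not be decided by the endothelial median of -0.0865. That list was chosen with its values known, and it lay near the median over all kept genes (-0.08). Of other cell types, astrocyte markers (0.20) and meningeal markers were higher, as such a loss would give, while choroid plexus markers were lower, as it would not. A difference in the regions included at dissection is a candidate explanation: the second cortical list had a median of -0.23 with 14 of 19 genes lower, as that would need, while the second striatal list was at 0.14 with 11 of 14 higher, between the bounds set for and against, and these medians were -0.13 and 0.24 with median centring and -0.22 and 0.04 with the 75th percentile filter, which kept 11 and 7 genes, so which bound a list meets depends on scaling and filter. An ethanol response of the hippocampus alone stays open as well, because the striatal median of 0.47 between hippocampus and forebrain after ethanol rests on 1 array per group. Such a response and regional makeup cannot be told apart here.

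Y-linked genes differed in opposite directions in the tissues, at 0.89, 0.79 and 0.57 for Eif2s3y, Uty and Kdm5d in forebrain and -0.33, -0.35 and -0.26 in hippocampus. Unequal numbers of male and female embryos in the samples may account for this: Xist differed by -0.38 in forebrain, opposite to the Y-linked genes, and by 0.05 in hippocampus. Every array read both Xist (11.10 to 11.48) and the Y-linked genes, so each may hold RNA of both sexes, but the sexes of the embryos are not in the labels. Between tissues, Eif2s3y, Uty and Kdm5d differed by 0.85, 0.69 and 0.62 (hippocampus minus forebrain) after PBS and by -0.37, -0.45 and -0.21 after ethanol. The mix of sexes may therefore differ between the tissues of a treatment too, and the fit over both tissues does not account for sex. An ethanol effect on the sex ratio common to both tissues is argued against as the whole cause by a Y-linked median of -0.330 in hippocampus, opposite to forebrain.

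Replication-dependent histone genes were lower after ethanol in both tissues, with medians of -0.18 in hippocampus (12 of 15 lower) and -0.16 in forebrain (11 of 15 lower; with median centring -0.08 and -0.14, 9 and 11 lower), and 6 of them fell in the limma test over both tissues with Benjamini-Hochberg adjustment over this list, which was assembled after its values were seen. Poorer recovery or labelling of short RNAs without a poly(A) tail is argued against as the whole cause in forebrain by a small nucleolar RNA median of -0.00561 (lower quartile -0.13, above the histone median). In hippocampus it stays open, since 36 of 38 such genes were lower there with a median of -0.32 (31 and -0.22 with median centring). Probe sets of 92 microRNA genes, which do not measure mature microRNAs, were not lower there as a group (47 lower, median -0.01). Fewer dividing cells could contribute: cell cycle genes had a forebrain median of -0.0749, slightly short of the bound set for that explanation, and the spread of their differences leaves it open. Near-identical histone copies share probe sequence, so the number of separate genes behind this is uncertain.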

How the results depend on the processing

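The 1.5-fold counts under other filters and scalings were added after seeing the data, as was the setting without regional, cell type and sex-linked list members. That setting kept the 2-fold hippocampus counts at 6 and 1, but none of these genes is in the lists left out. It therefore could not change the counts and says nothing about regional makeup or sex. The cause of a change was not tested except where fewer genes or another threshold makes it. Of alternatives for counts 78 stayed within 1.5 times and 45 moved, for single genes 248 and 36, and for list medians 492 and 50, with 2 more reversing. Some counts could not move, such as 2-fold counts of 0 at 3-fold or under a stricter filter, so the 78 overstate stability. Of 51 list medians apart from random lists, 40 were apart under every alternative run, though centring cannot change such a call. The 11 that were not are Wnt signalling, neuropeptides and progenitors (ethanol in hippocampus), retinoid metabolism, cell cycle and choroid plexus (ethanol in forebrain), unfolded protein genes (tissue, PBS) and chromatin, cholesterol, immediate early and progenitor genes (tissue, ethanol). With the 75th percentile filter 2 medians reversed: chromatin genes between tissues after ethanol to -0.0331 and neuropeptides after ethanol in hippocampus to -0.00690.

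In hippocampus the 2-fold counts of 6 higher and 1 lower became 54 and 47 at 1.5-fold, 1 and 0 at 3-fold, 10 and 0 with median centring and 3 and 0 with the 75th percentile filter, and the higher count was 10 without a filter. Its 1.5-fold counts became 116 and 19 with centring, 88 and 31 after quantile normalization, 23 and 30 with the 75th percentile filter and 131 and 77 without a filter. In forebrain the counts of 0 became 5 and 3 at 1.5-fold, and these became 1 and 1 with the 75th percentile filter and 24 and 22 without a filter, with 1 lower under centring. Genes 2-fold apart in both tissues went from 0 to 3 at 1.5-fold. Limma's 0 and 0 genes that rose and fell with ethanol became 1 and 1 with centring, 5 and 2 with the 75th percentile filter and 12 and 2 after quantile normalization. At an adjusted p of 0.1, without a trend, without a filter and with probe set means it stayed at 0 and 0. Limma's 12 genes higher and 112 lower in hippocampus than forebrain became 36 and 238 at an adjusted p of 0.1, 21 and 45 with centring, 2 and 25 without a trend, 4 and 33 without a filter and 70 and 346 after quantile normalization, and the higher count was 23 with the 75th percentile filter. Of the splits into 2 and 2 arrays, the treatment split went from 0 to 1 without a filter, the tissue split from 6 to 3 and the remaining split from 1 to 0 with the 75th percentile filter. The pseudocount alternatives were not run, since the values are already log2, and leaving out an array was not possible with 1 array per group. Weak signals limit the low end. Each 1.5-fold count is higher once genes below the filter at 7.11 are let in, but adding genes cannot lower a count.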

Other observations

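Of 38 small nucleolar RNA genes, which guide the modification of ribosomal and spliceosomal RNA, 36 were lower after ethanol in hippocampus (median -0.32) and 20 in forebrain (median -0.01, above 0 after either rescaling), and 37 were higher in hippocampus than forebrain after PBS (median 0.14) against 12 after ethanol (median -0.08). Examples in hippocampus were Snora52 at -0.63, Snord104 at -0.63 and Snora30 at -0.53. Probe sets assigned to the microRNA genes Mir18 and Mir20a read -0.80 and -0.52 in hippocampus, against -0.15 and 0.15 in forebrain. MicroRNA genes as a whole were not lower: of 92, 47 were lower in hippocampus (median -0.01) and 48 in forebrain (median -0.02), and Mir692-1 was higher by 0.51 and 0.58. These genes and groups were chosen after values were seen, and the array does not measure mature microRNAs.

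Some astrocyte markers were higher after ethanol in both tissues. Apoe differed by 0.55 in hippocampus and 0.12 in forebrain, Aqp4 by 0.50 and 0.16, Aldh1l1 by 0.36 and 0.18 and Sparcl1, a secreted matrix protein gene, by 0.35 and 0.11, whereas Aldoc was at -0.15 and 0.09, Slc1a2 at 0.20 and -0.03 and Gja1 at 0.13 and -0.02. Among oligodendrocyte lineage genes the lineage factor Sox10 was at 0.34 in hippocampus and -0.09 in forebrain, Olig2 at -0.10 and 0.11, the myelin enzyme gene Cnp at 0.26 and 0.23 and Olig1 at 0.17 and 0.30, and that list stood apart in forebrain but not in hippocampus (percentile 96.5).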
